A study of Macaca fascicularis and Homo sapiens with 55 samples.

How the data were processed

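The series combined single-cell RNA-seq of ovaries from 8 cynomolgus monkeys with bulk RNA-seq of KGN, a human granulosa cell line. The monkeys were 4 young animals (YF1 to YF4) and 4 aged animals (OF1 to OF4). Per the labels' protocols, single cells were picked by mouth pipette and libraries were made by STRT-seq, in which each cell carries an 8 nt barcode and each captured molecule an 8 nt unique molecular identifier (UMI). The pooled cDNA was amplified with 13 cycles for oocytes and with 19 to 21 cycles for somatic cells, per the labels. The bulk libraries were made from KGN cells with a negative control, a knockdown of IDH1 or a knockdown of NDUFB10, untreated or treated with H2O2, with 2 libraries in each of the 6 groups. The dose and time of H2O2 and the reagents of the knockdown were not given in the sources used here.

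The values deposited by the authors are whole-number UMI counts per gene and cell for the monkey libraries and whole-number read counts per gene for the KGN libraries. Per the submitters' processing notes, CASAVA 1.8, TopHat2 2.0.12 and HTSeq were used with the human build hg19. The notes do not tie a tool to a data type, and the genome used for the monkey reads is not given in the sources used here. The series-wide merged table, the barcode table and the third column of the KGN files were not used here. Each monkey file held 21136 features, of which 92 were ERCC spike-in RNAs and 21044 were genes. Identifier-only names covered 5024 genes and 15.41% of the gene UMIs, and such genes were tested and counted but not named. Spike-in RNAs took 11.53% of all UMIs and stayed out of library sizes and tests.

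The monkey files held 3521 cells, beside about 3500 cells in the series' own description, which states no filter. Cells with at least 700 genes and 3000 UMIs were kept, which left 2872 cells. No doublet caller was run, because the cells were picked one at a time. All kept cells were first clustered in scanpy 1.11.5 without correction (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.5), and the 419 cells in clusters with oocyte markers were taken as oocytes. The other cells were clustered again (2438 cells, with 15 left out from libraries that held too few), with 12 components and resolution 1.0. Before that, ComBat adjusted the mean and the spread of each of 1000 variable genes per library, which is called centring here. The centring was chosen after the clusters had been seen and before any age test, because 10 of 26 clusters of the first round took at least 75% of their cells from 1 library. Of 5 settings compared for the somatic cells, the setting used left the smallest share of cells unnamed (26.9%), and the others left up to 38.7%. Clusters were named from 14 classes of marker genes. A name needed at least 3 detected markers of its class, each in at least 25% of the cells, and the thresholds on the marker scores were set after the clusters had been seen. Cell types are therefore rebuilt, and called by name only in the sense of carrying those markers.

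UMIs were summed per animal and cell type, because animals and not cells are the replicates. An animal entered a cell type with at least 10 cells, and the alternative with a single oocyte cluster with at least 5. Age was tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05, each cell type in its own fit. All 12 KGN libraries shared 1 edgeR fit of 14659 genes of the 24153 in the files, and 10 contrasts were tested. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists and marker classes with at least 5 tested members. The 22 lists covered antioxidant enzymes, respiratory complex I, respiratory complexes II to V, the citric acid cycle, glycolysis, cytosolic ribosomal proteins, p53 targets, apoptosis effectors with the BCL2 family, the cell cycle, DNA repair with cohesion, the unfolded protein response, and immediate early genes with the dissociation response. They further covered inflammatory and secretory factors, interferon response with antigen presentation, steroidogenesis, cholesterol synthesis and uptake, folliculogenesis with the TGF-beta family, collagens and matrix, oocyte and maternal effect genes, early stage and late stage oocyte genes, and NF-kB with stress transcription factors. Shares of cell types per animal were compared with an exact two-sided permutation test. In the age and KGN comparisons, CPM values scale UMIs or reads to the TMM-adjusted total of the animal's summed cells or of the library. Those of macrophages, of genes from other tissues and of the test for mixed RNA scale to the plain total. Log2 differences come from the fits. Each standard error (SE) is the absolute log2 difference divided by the square root of the F statistic of edgeR's test. For large changes that rest on few reads, as in the knocked-down targets, such an SE can understate the error.

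The groups, tests, lists, markers and the rule for named genes were fixed before the data were examined. Per comparison with called genes, the rule named the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, with at least median expression and with complete separation of the libraries. It added up to 3 called members with the smallest p from each list. IDH1 and NDUFB10 were named in every comparison, GPX1, GSR and PRDX4 in oocytes, and AMH and FOXL2 in granulosa cells. Where no gene was called, the 3 genes with the smallest p in each direction were given as values. From these, the text shows a choice per list, and some genes that the rule names are not reported here.

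The edgeR and DESeq2 steps were tested on simulated counts with known changes before use. In oocytes, edgeR recovered 59.2% of genes changed 4-fold and 100% of genes changed 16-fold. In granulosa cells it recovered 8.9% at 4-fold and 54.8% at 16-fold, in endothelial cells 14.6% at 16-fold and in T and NK cells 6.4%. False genes made up at most 3.1% of edgeR's calls in the monkey simulations, and 17.9% to 51.4% of those of DESeq2 1.42.0, which served only as an alternative. In the KGN simulations, edgeR recovered 58.3% to 89.4% of genes changed 2-fold, with 4.4% to 8.8% false among its calls.

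The alternatives were DESeq2, no filter on low counts, a stricter cell filter of 1500 genes and 6000 UMIs, a minimum of 20 cells per animal, equal weight for every cell, a single oocyte cluster, a single picked fraction, and each animal or library left out. For KGN they also included the replicate number as a block, a fit of the compared groups alone, and a minimum 2-fold change. Further ones were chosen after seeing the data: cell types without centring, leaving out the libraries that stood apart before centring, counting each gene once per cell, and camera under the other settings. Intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9.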

Results

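Ovarian cells of 4 young monkeys (ages 4 to 5 in the labels, which give no unit) and 4 aged monkeys (ages 18 to 20) were profiled in 43 single-cell libraries. The libraries came from large cells of the cortex (13 libraries), small cells of the cortex (12), the medulla (10) and picked oocytes (8). Library totals ran from 19040 to 29868614 UMIs with a median of 3808216, and totals per animal from 12135586 to 51141958. The KGN part held 12 libraries of 6729890 to 12046302 reads (median 8715416) with 16151 to 18958 genes detected. In each pair of KGN libraries the counts differed by more than sampling noise (chi-square per gene 1.73 to 6.97). The labels call these libraries biological replicates, and beyond that nothing says that they came from separate cultures, so p-values then measure only the spread between these libraries, which may be technical.

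The first question was which cell types the ovaries held and whether their makeup differed with age. Among 2872 kept cells there were 419 oocytes, 330 granulosa cells, 542 stromal cells, 505 smooth muscle cells, 137 endothelial cells, 66 macrophages, 170 T and NK cells and 32 epithelial cells. Granulosa clusters were led by TNNI3, F3, INHA, CYP19A1 (the aromatase that makes oestrogen) and AMHR2, and stromal clusters by TCF21, C7 and STAR or by LUM, DPT and COL1A1. Smooth muscle clusters were led by ACTG2 and MYLK or by MYL9 and RERGL, endothelial cells by RNASE1, VWF, PECAM1 and EGFL7, macrophages by AIF1, IL1B and LYZ, and epithelial cells by ITLN1 and MSLN. A further 656 cells stayed unnamed, at 32.8% ± 22.1 (SD, n = 4) of the somatic cells of young animals and 25.1% ± 12.5 (n = 4) of those of aged animals. After centring, no cluster was named theca, pericyte, B or plasma, mast, glial or erythroid from the markers fixed for those classes. The first clustering, without correction, had named a cluster of 6 cells from 1 young animal pericyte, led by COX4I2, RGS5 and KCNJ8. FOXL2, a transcription factor that maintains granulosa identity, had 0 UMIs in all 330 granulosa cells and in all 2872 cells of every type, so these libraries do not show whether it could be detected.

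The share of each cell type among the named somatic cells was compared with exact two-sided permutation tests (70 groupings of 4 against 4 animals). Their smallest possible p of 0.0286 becomes 0.2 for a single type when adjusted over 7 types, so no single type could pass. Endothelial cells made up 11.7% ± 4.50 (SD) in young and 6.25% ± 3.38 in aged animals (exact p = 0.114, adjusted p = 0.533 over 7 types), and macrophages 6.75% ± 5.73 and 1.81% ± 0.815 (exact p = 0.171, adjusted p = 0.533). Granulosa cells stood at 21.0% ± 10.7 and 19.3% ± 8.12, stromal cells at 25.7% ± 8.58 and 32.3% ± 9.88, and smooth muscle cells at 23.1% ± 10.96 and 30.8% ± 3.90. T and NK cells held 8.55% ± 8.01 and 7.59% ± 6.73, and epithelial cells 3.17% ± 3.66 and 1.96% ± 2.09. Within the small-cell fraction of the cortex, granulosa cells made up 17.6% ± 10.9 in young and 5.43% ± 3.43 in aged animals (exact p = 0.114, adjusted p = 0.4). The other fractions differed from this, with 29.4% ± 13.5 and 28.0% ± 13.5 among the large cells of the cortex (exact p = 0.886), and 0.769% ± 1.09 in 2 young and 14.0% ± 14.3 in 4 aged animals in the medulla (exact p = 0.267, with 15 groupings). Cells were picked by hand into fractions, so these shares describe the picked cells.

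**Figure D1:**
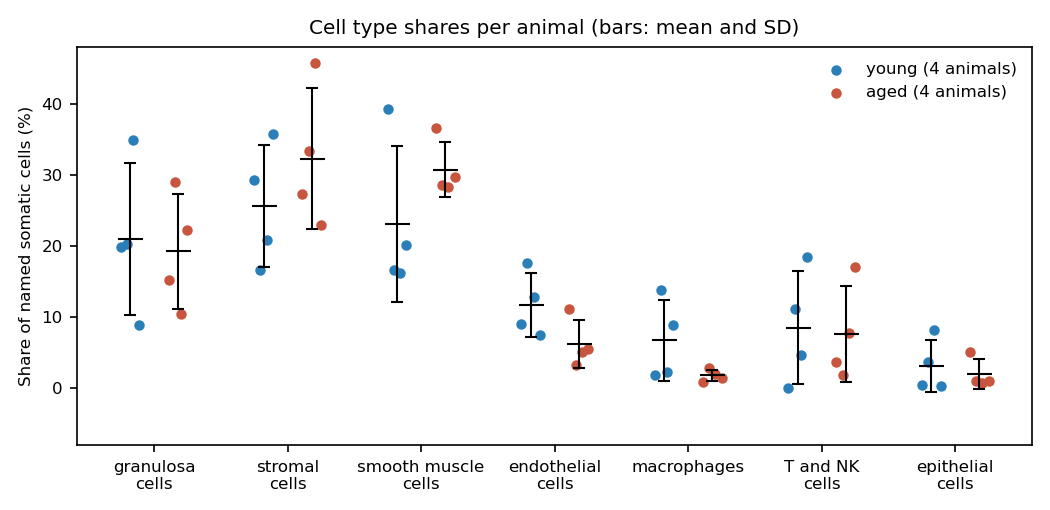
Share of each cell type among the named somatic cells, in percent, for each young and aged animal; points are animals and bars give mean and SD. Endothelial cells averaged 11.7% in young and 6.25% in aged animals, with overlapping points.

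In oocytes, the comparison of 3 young and 4 aged animals asked which transcripts follow age in the germ cell. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0 of 13654; 232 at an unadjusted p under 0.05; DESeq2 called 6). The antioxidant genes named in advance were all lower in aged oocytes without passing: GPX1, which reduces peroxides with glutathione, at 1211 ± 797 and 691 ± 126 CPM in young and aged animals (log2 difference -0.81 ± 0.39 SE). GSR, which regenerates glutathione, stood at 27.7 ± 7.41 and 19.6 ± 6.92 CPM (-0.50 ± 0.35). PRDX4, a peroxidase of the endoplasmic reticulum, stood at 308 ± 150 and 182 ± 39.8 CPM (-0.75 ± 0.33). YF1 carried much of this: it held GPX1 at 2131 CPM, against 743 and 760 in YF3 and YF4, and without it the log2 differences were -0.13 for GPX1, -0.26 for GSR and -0.29 for PRDX4. NDUFB10, a subunit of respiratory complex I, was at 218 ± 7.38 and 172 ± 26.8 CPM (-0.34 ± 0.21), and IDH1, the cytosolic isocitrate dehydrogenase that makes NADPH, at 74.0 ± 21.4 and 78.5 ± 23.7 CPM (0.08 ± 0.30), with its sign turned with a single oocyte cluster (-0.13) and without OF2 (-0.15) or YF1 (-0.078). In edgeR the adjusted p of each of these 5 genes was 1.0.

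The oocyte genes with the smallest p, given as values since none passed, were ABO, the glycosyltransferase of the blood groups, TMEM260, an enzyme of O-mannosylation, and NOX1, which makes superoxide, on the higher side. ABO stood at 0.548 ± 0.413 CPM in young and 5.84 ± 2.99 in aged animals (log2 3.36 ± 0.71), TMEM260 at 106 ± 12.3 and 229 ± 56.5 (1.11 ± 0.25), and NOX1 at 2.16 ± 0.300 and 7.13 ± 1.55 (1.72 ± 0.41). On the lower side, TMEM242, an assembly factor of ATP synthase, stood at 134 ± 23.2 and 60.4 ± 6.71 CPM (-1.14 ± 0.22). The cytokine-like FAM3B stood at 41.1 ± 19.2 and 11.8 ± 2.41 CPM (-1.80 ± 0.36), and the muscle ankyrin protein ANKRD2 at 36.6 ± 8.64 and 14.2 ± 4.03 (-1.37 ± 0.32).

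As groups, mitochondrial and ribosomal genes of oocytes lay lower in aged animals under camera's preset correlation, with no member called, over all genes or adjusted over the list alone. Of the complex I genes, 25 of 26 had a negative difference (median log2 -0.24, adjusted p = 1.69e-06), and of complexes II to V, 20 of 20 (median -0.30, adjusted p = 2.27e-06). These calls did not hold with an estimated correlation, at adjusted p = 0.321 for both, nor when each cell counted a gene once. Ribosomal protein genes were negative in 51 of 52 (median -0.34, adjusted p = 3.78e-09; adjusted p = 0.711 with an estimated correlation), and citric acid cycle genes in 14 of 18 (median -0.21, adjusted p = 0.0145; adjusted p = 0.321 with an estimated correlation). Positive were 13 of 18 immediate early genes (median 0.44, adjusted p = 0.0294; adjusted p = 0.711 with an estimated correlation) and 16 of 21 folliculogenesis genes (median 0.20, adjusted p = 0.0294; adjusted p = 0.321 with an estimated correlation). Oocytes of the animals lay in different clusters: 1 cluster held 89.66% of those of OF1 and 0% of those of YF4, and another 62.5% of those of YF3 and 0% of those of YF1 and YF4. Within a single cluster (3 young and 3 aged animals, OF2 with only 5 oocytes, below the minimum of 10 used elsewhere), the preset correlation called only ribosomal genes among these 6 lists (adjusted p = 0.0448), with the other 5 at adjusted p = 0.225 to 0.753. The 5 tested macrophage markers were all positive (median 0.45, adjusted p = 0.0275; adjusted p = 0.205 with an estimated correlation). Antioxidant enzymes, with 23 of 38 negative, were not called (median -0.16, adjusted p = 0.161).

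The other lists were not called in oocytes under camera's preset correlation. Their adjusted p was 0.595 for p53 targets, 0.797 for apoptosis effectors, 0.945 for glycolysis, DNA repair, cholesterol synthesis and NF-kB factors alike, and 0.822 for the cell cycle and for collagens. It was 0.760 for the unfolded protein response and for oocyte and maternal effect genes, 0.0586 for inflammatory factors, 0.0878 for the interferon response and 0.977 for steroidogenesis. Early stage and late stage oocyte genes, which mark follicles at the start and at the end of growth, both stood at 0.945. Median, mean and test differed in sign for steroidogenesis, cholesterol, collagen, NF-kB and early and late stage oocyte genes, none of them called. Per oocyte, the median mitochondrial share of UMIs was 6.29% ± 2.18 (SD, n = 3) in young and 8.53% ± 1.11 (n = 4) in aged animals (exact two-sided permutation p = 0.143). Among 35 groupings the smallest possible p was 0.0286. Median UMIs per oocyte were 159027 ± 101703 and 104491 ± 33855 (exact p = 0.486).

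In granulosa cells, the somatic cells that nurse the oocyte, IDH1 and NDUFB10 were the genes of interest because the study knocked them down in KGN cells. With 4 young and 4 aged animals, NDUFB10 stood at 399 ± 130 CPM in young and 193 ± 61.1 in aged animals (log2 -1.05 ± 0.42) and IDH1 at 185 ± 63.9 and 103 ± 60.7 (-0.84 ± 0.56). OF1 held IDH1 at 27.1 CPM, against 97.8 to 174.9 in the other aged animals. AMH, the hormone of growing follicles, stood at 297 ± 124 and 157 ± 129 CPM (-0.92 ± 0.62), and its sign turned when cell types were taken without centring. Among aged animals AMH ran from 23.2 CPM in OF1 to 282 in OF4. None of the 3 passed edgeR's test after Benjamini-Hochberg adjustment (adjusted p = 0.999), and edgeR called 0 of 8654 genes (294 at an unadjusted p under 0.05; DESeq2 called 33). Among the genes with the smallest p, the matrix proteoglycan DCN (187 ± 51.6 and 765 ± 671 CPM) and the signalling adaptor RAPGEFL1 (834 ± 348 and 2412 ± 1218) were higher. DCN, a stromal marker, lost its direction when each cell counted a gene once, and its log2 difference was 1.265 in place of 2.036 without OF3. The kinase gene STK33 had 0 UMIs in young and 13.0 ± 14.2 CPM in aged animals. Lower were the adhesion-linked FOCAD (46.4 ± 46.8 and 1.04 ± 0.906 CPM), the kinetochore gene CENPF (223 ± 156 and 43.8 ± 25.5) and the TGF-beta binding LTBP4 (70.1 ± 46.8 and 7.97 ± 5.01).

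Of 29 cell cycle genes in granulosa cells, 22 were lower in aged animals (median log2 -0.86, adjusted p = 0.00474; adjusted p = 0.872 with an estimated correlation). Of 52 ribosomal genes, 50 were lower (median -0.18, adjusted p = 0.00474; adjusted p = 0.872 with an estimated correlation). Within the large-cell fraction of the cortex, neither list was called, at adjusted p = 0.1665 for the cell cycle (median -0.13) and adjusted p = 0.4311 for ribosomal genes (median 0.002, 25 of 52 lower). Antioxidant enzymes, complex I and cholesterol synthesis each stood at an adjusted p of 0.215 under the preset correlation, and steroidogenesis at 0.411. No member of any list was called, also when adjusted over the list alone.

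**Figure D2:**
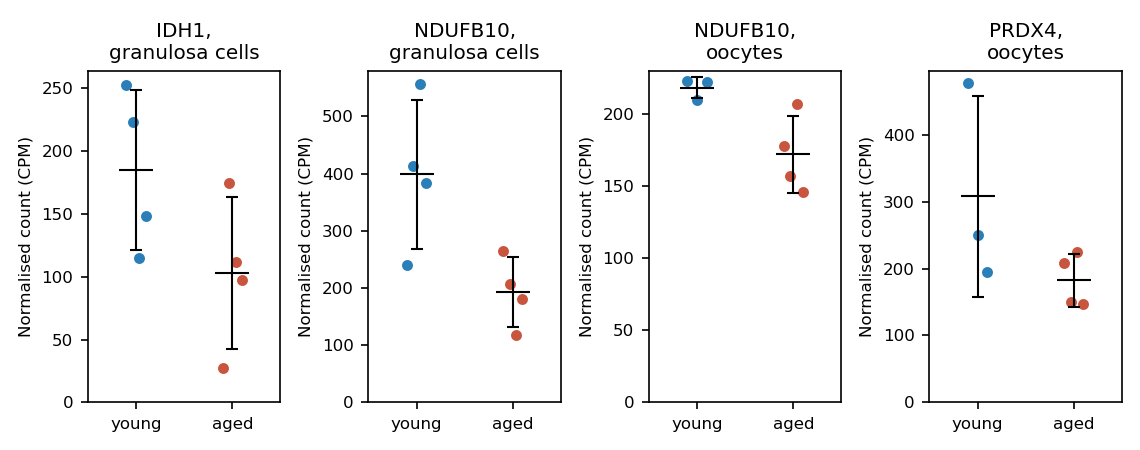
IDH1 and NDUFB10 in granulosa cells and NDUFB10 and PRDX4 in oocytes, in CPM of the summed cells, for each young and aged animal; points are animals and bars give mean and SD. NDUFB10 in granulosa cells averaged 399 CPM in young and 193 CPM in aged animals.

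In stromal cells, the fibroblast-like cells that hold the follicles (4 against 4 animals), edgeR with Benjamini-Hochberg adjustment called 0 of 9054 genes (423 at an unadjusted p under 0.05; DESeq2 called 36). CBR1, which reduces carbonyls formed in oxidative stress, stood at 9.73 ± 4.45 CPM in young and 87.7 ± 26.6 in aged animals (log2 3.16 ± 0.89), and the spindle checkpoint gene MAD2L1 at 1.05 ± 1.18 and 28.7 ± 9.69 (5.09 ± 1.45). C1orf109, a growth-linked gene, stood at 1.36 ± 1.70 and 37.1 ± 35.6 CPM. The migration-linked CCDC141 (95.1 ± 175 and 0.054 ± 0.109 CPM), the ubiquitin ligase gene UBE4B (251 ± 427 and 8.38 ± 5.62) and the calcium channel gene ITPR1 (522 ± 773 and 25.4 ± 6.31) were lower, each with a spread in young animals above its mean. CCDC141 had the smallest adjusted p (0.333). YF3, with 18 cells and 615546 UMIs, held CCDC141 at 358 and UBE4B at 891 CPM. Without YF3 the log2 differences were -6.56 in place of -10.2 for CCDC141, -2.11 in place of -4.89 for UBE4B and -2.46 in place of -4.36 for ITPR1. OF1 held C1orf109 at 90.3 CPM, and without it that difference was 3.62 in place of 4.51. IDH1 differed by -0.78 ± 0.73 and NDUFB10 by -0.56 ± 0.58 in log2 (-0.262 and -0.019 without YF3). With at least 20 cells per animal the sign of ITPR1 (0.20) and NDUFB10 (0.42) turned, as did that of NDUFB10 without centring (0.055) and that of IDH1 with equal weight for every cell (0.14). Collagen and matrix genes were lower in 20 of 27 (median -0.60, adjusted p = 0.0922) and steroidogenic genes higher in 14 of 15 (median 0.80, adjusted p = 0.226), and camera called no list. Markers of smooth muscle were higher in 7 of 7 (adjusted p = 0.170).

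In smooth muscle cells, the contractile cells of vessels and stroma (4 against 4 animals), edgeR with Benjamini-Hochberg adjustment called 0 of 7860 genes (434 at an unadjusted p under 0.05; DESeq2 called 13). The metabolic coactivator CRTC1 (0.244 ± 0.297 and 19.3 ± 14.0 CPM in young and aged animals), the death receptor FAS (2.32 ± 2.10 and 47.9 ± 62.4) and the secreted CHI3L1 (43.7 ± 44.1 and 368 ± 296) were higher in aged animals. C11orf74, a ciliary transport gene (203 ± 365 and 2.39 ± 3.49), and ATM, the kinase that senses DNA breaks (124 ± 121 and 6.17 ± 3.66), were lower. OF2 held FAS at 141 CPM, and YF3, with 14 cells and 347894 UMIs, held C11orf74 at 750 CPM. Without OF2 the log2 difference of FAS was 2.62 in place of 4.09, and without YF3 that of C11orf74 was -3.11 in place of -6.47 and that of ATM -3.44 in place of -4.305. IDH1 differed by -0.94 ± 0.93 and NDUFB10 by 0.18 ± 0.62 in log2, and the sign of NDUFB10 turned in DESeq2 (-0.028). Genes of cholesterol synthesis and uptake were higher in 12 of 15 (median log2 1.44, adjusted p = 5.46e-05; adjusted p = 0.920 with an estimated correlation). Ribosomal genes were lower in 41 of 52 (median -0.29, adjusted p = 6.3e-05; adjusted p = 0.934 with an estimated correlation) and collagen and matrix genes in 19 of 24 (median -0.60, adjusted p = 0.0101; adjusted p = 0.920 with an estimated correlation).

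In endothelial cells, which line the vessels (4 young against 3 aged animals), edgeR with Benjamini-Hochberg adjustment called 0 of 6702 genes (370 at an unadjusted p under 0.05; DESeq2 called 6). ALAS1, the first enzyme of haem synthesis, stood at 6.55 ± 5.57 CPM in young and 171 ± 193 in aged animals, the lysosome gene LYST at 22.5 ± 28.7 and 659 ± 1033, and EDN1, the vasoconstrictor endothelin, at 94.9 ± 32.4 and 741 ± 624 (log2 2.94 ± 0.85). The Golgi gene YIPF4 (423 ± 736 and 3.97 ± 1.66) and the coactivator CRTC3 (916 ± 1678 and 5.74 ± 9.33) were lower, and the small GTPase RAP2A stood at 65.7 ± 50.3 CPM in young animals and at 0 UMIs in aged animals. YF3 entered with only 11 cells and 122247 UMIs. It held YIPF4 at 1526 and CRTC3 at 3430 CPM, against at most 111 and 170 in the other young animals. Without YF3 the log2 difference of CRTC3 was -3.73 in place of -7.25. That of LYST was 1.47 in place of 4.81 without OF1, and that of ALAS1 2.98 in place of 4.44 without OF3. IDH1 differed by -1.35 ± 1.29 (-1.99 without OF3) and NDUFB10 by 0.53 ± 0.73 in log2. Immediate early genes were positive in 17 of 19 (median 0.80, adjusted p = 0.00638; adjusted p = 0.781 with an estimated correlation) and interferon response genes in 11 of 20 (median 0.65, adjusted p = 0.0254; adjusted p = 0.781 with an estimated correlation).

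T and NK cells could be compared in 2 young (YF2, YF4) and 2 aged animals (OF3, OF4). Of the cells from young animals, 41 of 70 lay in a cluster led by the cytotoxic genes GNLY, CCL5 and NKG7, which drew 92.9% of its cells from the medulla library of YF4. Of those from aged animals, 99 of 100 lay in a cluster led by CD69, CXCR4 and GZMK. edgeR with Benjamini-Hochberg adjustment called 0 of 5932 genes (236 at an unadjusted p under 0.05; DESeq2 called 17). The activation marker CD83 stood at 42.1 ± 50.5 CPM in young and 849 ± 748 in aged animals, C15orf48, a subunit of cytochrome c oxidase, at 66.6 ± 78.3 and 1012 ± 913, and BAG1, a chaperone partner, at 0 UMIs and 132 ± 170. The mitochondrial ACSF3 (199 ± 253) and ZNF683, a factor of resident T cells (129 ± 139), had 0 UMIs in aged animals, and RUNDC1, a p53-linked gene, stood at 240 ± 326 and 0.29 ± 0.411 CPM. IDH1 differed by -1.14 ± 2.26 and NDUFB10 by -0.64 ± 1.12 in log2. Without single animals IDH1 ran from -2.566 (without OF3) to -0.004 (without YF4), with -1.80 without YF2 and -0.428 without OF4, and NDUFB10 from -1.20 (without OF4) to -0.144 (without YF4), with -0.202 without OF3, and the sign of NDUFB10 turned without centring (0.02), without the libraries that stood apart (0.69) and with each gene counted once per cell (0.31). T and NK markers were lower in 8 of 10 (adjusted p = 0.0649), and camera called no list. In simulated T and NK cells edgeR recovered 6.4% of 16-fold changes, and camera did not call a list shifted 2-fold, so these counts of 0 exclude little. No aged animal held 10 macrophages, so macrophages were not tested. In the young animals YF2 and YF4 their CD68, a lysosomal marker of macrophages, stood at 1333 and 228 CPM and NDUFB10 at 106 and 119. Other macrophage genes were lower in YF4 too, with C1QA at 274 CPM in YF2 and 0 UMIs in YF4, CD14 at 338 and 114 CPM, and LYZ at 2956 and 1606. Of the 26 macrophages of YF4, 5 were left without the libraries that stood apart.

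The KGN libraries asked what granulosa cells lose when IDH1 or NDUFB10 is reduced, alone and under H2O2. The targets were measured first. IDH1 stood at 234 and 233 CPM in the untreated control libraries and at 252 and 264 with H2O2, against 8.95 and 9.67 in the IDH1 knockdown and 2.07 and 3.38 in the same knockdown with H2O2. NDUFB10 stood at 57.4 and 57.5 CPM in the control and at 64.9 and 60.7 with H2O2, against 3.02 and 3.89 in the NDUFB10 knockdown and 2.39 and 1.65 with H2O2. The IDH1 knockdown left NDUFB10 at 57.3 and 48.5 CPM (58.5 and 59.99 with H2O2). The NDUFB10 knockdown also held less IDH1, at 85.0 and 77.8 CPM untreated and 100.1 and 98.8 with H2O2.

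**Figure D3:**
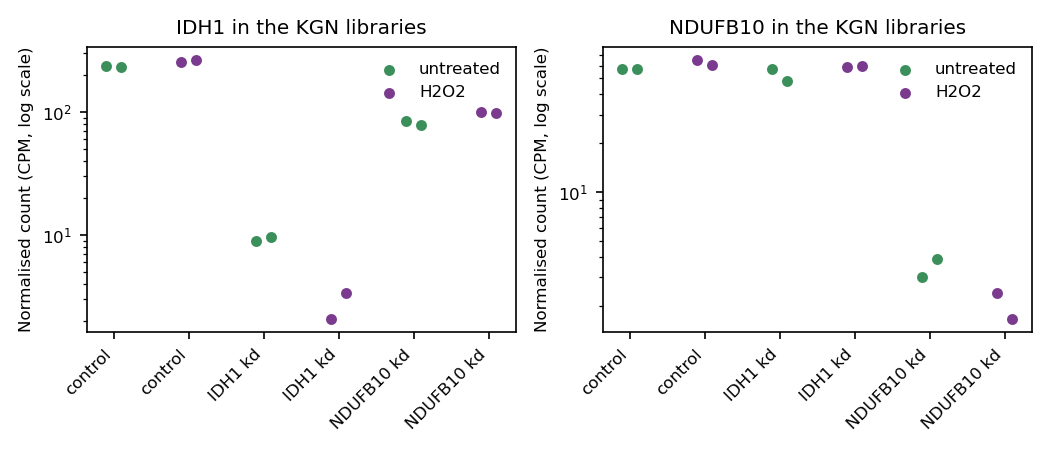
IDH1 and NDUFB10 in CPM, on a log scale, in each of the 12 KGN libraries, by knockdown and H2O2 treatment; points are libraries. Each target is lowest in its own knockdown, and IDH1 is also lower in the NDUFB10 knockdown, at 85.0 and 77.8 CPM against 234 and 233 in the control.

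In untreated cells, the tested cell cycle genes were lower and most collagen and matrix genes higher in the IDH1 knockdown than in the control. Neither list call of camera held with an estimated correlation, as given below. The knockdown reagent is not given, so loss of IDH1 cannot be told from other effects of the reagent. In edgeR with Benjamini-Hochberg adjustment, 5340 of 14659 genes passed (2836 higher, 2504 lower; n = 2 libraries per group here and in every KGN group), and 1062 of them changed at least 2-fold (415 higher, 647 lower). IDH1 itself fell by 4.64 ± 0.12 on the log2 scale. All 40 tested cell cycle genes fell (median log2 -2.27), among them CDC20, which starts anaphase (-3.08 ± 0.17), RRM2, which makes deoxynucleotides (-2.88 ± 0.13), TOP2A, which untangles DNA (-2.74 ± 0.12), and MKI67, a marker of dividing cells (-2.80 ± 0.12). The spindle genes NUSAP1 (-3.06 ± 0.17) and KIF11 (-2.89 ± 0.16) fell as well. Of DNA repair genes 17 fell and 1 rose of 31 (median -0.39), with FANCI (-2.39 ± 0.16) and BRCA1 (-2.09 ± 0.22), both of crosslink and break repair. The growth-linked RNA H19 fell by 3.35 ± 0.15. Among called genes with at least median expression and complete separation of the libraries, rises were led by complement C3 (1.92 ± 0.11) and the elastic fibre gene MFAP4 (1.77 ± 0.10). IGFBP4, which binds insulin-like growth factors (1.69 ± 0.10), the lysosomal glycoprotein GPNMB (1.68 ± 0.09), the pseudokinase SGK223 (1.65 ± 0.18) and the collagen gene COL1A2 (1.58 ± 0.07) followed.

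By list, collagens rose in 20 and fell in 2 of 30 (median 0.38), with COL3A1 (0.96 ± 0.07), and the 6 tested stromal markers rose in 5 (median 1.02). Ribosomal protein genes rose in 64 and fell in 1 of 74 (median 0.43), with RPL28 (0.96 ± 0.08). Of 26 p53 targets, 16 rose and 5 fell (median 0.44), with SESN2, which restrains mTOR (1.41 ± 0.10), and the death gene BBC3 (1.34 ± 0.13). Of 20 glycolysis genes, 15 fell and 1 rose (median -0.45), with ENO1 (-0.81 ± 0.07) and LDHA (-0.83 ± 0.07). Antioxidant enzymes fell in 15 and rose in 5 of 43 (median -0.10), PGD at -0.74 ± 0.08 and PRDX4 at 1.06 ± 0.08, and cholesterol genes fell in 9 and rose in 1 of 22 (median -0.17), with STARD4, a sterol carrier (-1.09 ± 0.12). camera's preset correlation gave adjusted p = 3.62e-32 for the cell cycle, 1.15e-13 for ribosomal genes, 5.81e-06 for glycolysis, 6.37e-06 for DNA repair, 1.15e-05 for collagens, 0.000185 for stromal markers, 0.00141 for p53 targets, 0.0176 for antioxidant enzymes and 0.0213 for cholesterol genes. None held with an estimated correlation, at adjusted p = 0.0659 for the cell cycle and DNA repair and up to 0.255 for collagens. Adjusted over the list alone, 40 cell cycle, 67 ribosomal, 17 glycolysis, 24 collagen, 21 DNA repair, 22 antioxidant, 21 p53 and 10 cholesterol genes passed.

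The remaining lists moved both ways or little under IDH1 knockdown. Complex I fell in 9 and rose in 1 of 37 genes (adjusted p = 0.150), NDUFB3 at -0.82 ± 0.14, complexes II to V fell in 8 and rose in 4 of 38 (adjusted p = 0.352), and the citric acid cycle fell in 7 and rose in 2 of 23 (adjusted p = 0.161). The unfolded protein response rose in 10 and fell in 3 of 24 (adjusted p = 0.150), with DDIT3 (0.97 ± 0.12), and apoptosis effectors rose in 6 and fell in 3 of 23 (adjusted p = 0.472). Inflammatory factors rose in 7 and fell in 7 of 23 (adjusted p = 0.907), with the stress cytokine GDF15 (1.16 ± 0.11), and interferon genes rose in 6 and fell in 10 of 26 (adjusted p = 0.530), with IFIT3 (-1.39 ± 0.17). Immediate early genes rose in 8 and fell in 9 of 26 (adjusted p = 0.566), NF-kB factors rose in 4 and fell in 5 of 18 (adjusted p = 0.877), and folliculogenesis genes rose in 7 and fell in 8 of 28 (adjusted p = 0.974), with SMAD3 (-0.92 ± 0.08) and the activin antagonist FST (-0.84 ± 0.10). Steroidogenic genes rose in 3 and fell in 1 of 17 (adjusted p = 0.790), CYP19A1 at -0.65 ± 0.14. Median, mean and test differed in sign for immediate early genes and NF-kB factors. The 7 tested oocyte and maternal effect genes lay near the detection floor, with 1 higher (adjusted p = 0.580). NDUFB10 was not called (-0.12 ± 0.11). All these p-values are from camera with the preset correlation.

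In untreated cells, genes of cholesterol synthesis and uptake and of glycolysis were lower in the NDUFB10 knockdown than in the control. The knockdown reagent is not given, and these libraries also held less IDH1. Loss of NDUFB10 can therefore not be told from other effects of the reagent or from the lower IDH1. edgeR with Benjamini-Hochberg adjustment called 5134 genes (2647 higher, 2487 lower; 1078 at least 2-fold, 461 higher and 617 lower). NDUFB10 fell by 4.04 ± 0.17 on the log2 scale, and IDH1 fell by 1.52 ± 0.09 (edgeR adjusted p = 6.48e-17). SCD, which makes monounsaturated fatty acids, fell by 4.37 ± 0.09, the sphingosine phosphatase SGPP1 by 3.23 ± 0.16 and the transporter SLC12A8 by 3.08 ± 0.13. H19 had 2 and 3 reads in the knockdown libraries (0.297 ± 0.065 CPM, against 67.9 ± 6.696 in the control). Of 22 cholesterol genes, 21 fell and 1 rose (median -1.09, camera adjusted p = 1.12e-14), with the sterol sensor INSIG1 (-2.12 ± 0.10) and HMGCS1 of the mevalonate pathway (-2.06 ± 0.10). Of 20 glycolysis genes, 16 fell (median -0.78, adjusted p = 3.1e-09; adjusted p = 0.0734 with an estimated correlation), with PGK1 (-1.31 ± 0.07) and HK2 (-1.35 ± 0.08). Among called genes with at least median expression and complete separation of the libraries, rises were led by the secretory granule gene SCG2 (2.22 ± 0.15) and the differentiation inhibitor ID4 (1.97 ± 0.14). The ubiquitin ligase gene TRIM58 (1.87 ± 0.09), DTNA of the dystrophin complex (1.76 ± 0.15), the sialomucin PODXL (1.62 ± 0.08) and LZTS3 (1.59 ± 0.16), a postsynaptic gene, followed.

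Antioxidant enzymes fell in 23 and rose in 5 of 43 with NDUFB10 knockdown (median -0.43, camera adjusted p = 2.43e-05), with the mitochondrial dismutase SOD2 (-1.46 ± 0.09) and TXNRD1 (-1.07 ± 0.07). The antioxidant and cholesterol lists held with an estimated correlation, at adjusted p = 0.0159 and adjusted p = 0.00573. The unfolded protein response fell in 14 of 24 (median -0.31, adjusted p = 1.74e-05; adjusted p = 0.0734 with an estimated correlation), with HERPUD1 (-0.75 ± 0.09) and ASNS (-0.85 ± 0.10). Inflammatory factors fell in 14 and rose in 3 (median -0.83, adjusted p = 0.00320; adjusted p = 0.386 with an estimated correlation), with the vessel growth factor VEGFA (-1.59 ± 0.09), while IGFBP5 rose (1.28 ± 0.09). Interferon genes fell in 12 and rose in 4 (median -0.26, adjusted p = 0.0105; adjusted p = 0.317 with an estimated correlation), and citric acid cycle genes fell in 7 and rose in 2 (median -0.16, adjusted p = 0.0270; adjusted p = 0.114 with an estimated correlation), with PDHB (-1.04 ± 0.09). Cell cycle genes rose in 14 and fell in 2 (median 0.27, adjusted p = 0.0354; adjusted p = 0.725 with an estimated correlation), with MKI67 (0.51 ± 0.10). Adjusted over the list alone, 22 cholesterol, 29 antioxidant and 19 cell cycle genes passed. Complex I beyond NDUFB10 moved little, with 6 genes lower and 2 higher (adjusted p = 0.300), while UQCRC2 of complex III fell (-1.65 ± 0.10). Smooth muscle markers fell in 4 of 5 (median -1.14, adjusted p = 0.00258; adjusted p = 0.268 with an estimated correlation). STAR, which carries cholesterol into mitochondria (-1.04 ± 0.12), the activin subunit INHBB (-1.60 ± 0.12) and FST (-1.85 ± 0.10) fell, and TGFBR2 (1.34 ± 0.08) and COL3A1 (1.23 ± 0.07) rose.

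Set against each other in untreated cells, the knockdowns differed in 5890 genes in edgeR with Benjamini-Hochberg adjustment (3091 higher with IDH1 knockdown, 2799 lower). All 40 cell cycle genes were lower with IDH1 knockdown (median log2 -2.52), MKI67 by -3.31 ± 0.12 and RRM2 by -3.52 ± 0.13, and camera's adjusted p = 1.62e-29 held with an estimated correlation (adjusted p = 0.0436). Cholesterol genes were higher in 20 and lower in 1 of 22 (median 0.90, adjusted p = 1.01e-09; adjusted p = 0.0203 with an estimated correlation), SCD by 3.20 ± 0.09 and INSIG1 by 1.99 ± 0.10. The unfolded protein response was higher in 17 of 24 (median 0.46, adjusted p = 2.88e-06; adjusted p = 0.0436 with an estimated correlation), and DNA repair lower in 18 and higher in 4 (median -0.58, adjusted p = 7.29e-06; adjusted p = 0.0360 with an estimated correlation). Also higher were FBXO32, a ubiquitin ligase gene of muscle wasting (2.96 ± 0.11), the complement protease C1S (2.79 ± 0.10) and GDF15 (2.25 ± 0.12).

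Against the same control libraries, the log2 changes of both knockdowns correlated across genes at Pearson r = 0.394 (Spearman rho = 0.358) in untreated cells, where simulated unchanged groups against shared controls gave a mean r of 0.509 over 30 draws. Genes are not independent replicates. The covariance was 0.242 against a simulated 0.0864, a difference of 0.156. Both knockdowns called 2649 genes, with 1121 higher in both, 925 lower in both and 603 opposite, where independent lists would share 512 higher and 425 lower. The 2 control libraries were not split, since each part would hold a single library, so part of the excess may come from them.

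H2O2 in control cells raised p53 targets. edgeR with Benjamini-Hochberg adjustment called 7137 genes (3683 higher, 3454 lower; 2059 at least 2-fold, 1381 higher and 678 lower). All 26 tested p53 targets rose (median log2 1.73, camera adjusted p = 2.73e-18, adjusted p = 0.00610 with an estimated correlation). They included BTG2, an antiproliferative gene (3.71 ± 0.12), the cell cycle inhibitor CDKN1A (2.66 ± 0.07), MDM2, which degrades p53 (2.60 ± 0.10), and BBC3 (2.37 ± 0.12). HMOX1, which breaks down haem (3.43 ± 0.10), SRXN1 (1.33 ± 0.08) and GCLM of glutathione synthesis (1.19 ± 0.11) rose among 17 antioxidant enzymes that rose and 5 that fell (adjusted p = 0.0535). GDF15 (3.18 ± 0.10), the transcription factors ATF3 (3.15 ± 0.20) and FOSB (3.32 ± 0.33), and HMCN2, a matrix gene (6.88 ± 0.32), also rose. Cell cycle genes fell in 36 and rose in 2 of 40 (median -0.99), with CCNB1 (-2.02 ± 0.17), ASPM (-2.02 ± 0.13) and MKI67 (-1.58 ± 0.11). The scaffold gene MAGI1 (-2.24 ± 0.10), the mTOR inhibitor DDIT4 (-2.12 ± 0.12) and the adenosine receptor ADORA1 (-1.93 ± 0.14) also fell.

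Ribosomal genes rose in 72 of 74 with H2O2 (median 0.50, camera adjusted p = 4.03e-15), with RPL35A (0.75 ± 0.08), and complexes II to V in 19 of 38 (adjusted p = 0.00335). Cell cycle genes stood at an adjusted p of 6.59e-12. Cholesterol genes fell in 12 of 22 (median -0.36, adjusted p = 0.000309), with INSIG1 (-1.59 ± 0.10), DNA repair genes in 18 with 1 higher (adjusted p = 0.000202), and collagens in 19 with 4 higher (median -0.43, adjusted p = 0.000512), with COL5A1 (-1.07 ± 0.07). These 6 calls did not hold, at adjusted p = 0.0700 with an estimated correlation for cholesterol and DNA repair and up to 0.375. Complex I rose in 17 and fell in 4 (adjusted p = 0.0214; adjusted p = 0.407 with an estimated correlation), and stromal markers fell in 4 of 6 (adjusted p = 0.0273; adjusted p = 0.356 with an estimated correlation). Adjusted over the list alone, 39 cell cycle and 23 collagen genes passed. The unfolded protein response fell in 13 and rose in 4 of 24 (adjusted p = 0.0728), although PPP1R15A, which restores translation, rose (1.77 ± 0.09). FDXR, which feeds electrons to steroid synthesis, rose by 1.74 ± 0.10. IDH1 (0.15 ± 0.08) and NDUFB10 (0.13 ± 0.11) were not called.

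In the IDH1 knockdown, H2O2 changed 8439 genes in edgeR with Benjamini-Hochberg adjustment (4120 higher, 4319 lower; 1752 and 1009 with at least a 2-fold change). FOSB (6.27 ± 0.27), ATF3 (3.67 ± 0.16), BTG2 (3.48 ± 0.11) and HMOX1 (3.27 ± 0.10) rose, and p53 targets rose in 23 of 26 (median 1.61, camera adjusted p = 8.43e-13; adjusted p = 0.0173 with an estimated correlation). The contractile genes ACTA2 (-2.23 ± 0.10) and SYNPO2 (-2.19 ± 0.11) and the growth factor gene CTGF (-2.12 ± 0.10) fell. IDH1 itself was lower too (-1.80 ± 0.21), where an effect of H2O2 cannot be told from a deeper knockdown in the treated cells. In the NDUFB10 knockdown, H2O2 changed 8133 genes (3920 higher, 4213 lower; 1721 and 933 with at least a 2-fold change), with ATF3 (5.22 ± 0.17), the chemokine CXCL8 (5.36 ± 0.24), GDF15 (4.53 ± 0.11), SESN2 (3.79 ± 0.10), GADD45A (3.35 ± 0.08) and CDKN1A (3.24 ± 0.07) higher. TXNIP, which inhibits thioredoxin (-2.24 ± 0.11), and BMP4 (-2.12 ± 0.12) fell. The p53 targets rose in 24 of 26 (median 1.84, adjusted p = 7.11e-16; adjusted p = 0.00904 with an estimated correlation) and the unfolded protein response in 19 with 1 lower of 24 (median 1.22, adjusted p = 3.8e-08; adjusted p = 0.0430 with an estimated correlation). NDUFB10 was called lower by H2O2 within its own knockdown (-0.75 ± 0.29, edgeR adjusted p = 0.0268) and IDH1 higher (0.29 ± 0.09, edgeR adjusted p = 0.00603), and both calls were lost when single libraries were left out.

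The interaction asked whether H2O2 acted differently in a knockdown than in the control. Higher here means a larger signed log2 change with H2O2 in the knockdown, which for a gene that H2O2 lowers in the control can be a smaller fall. With NDUFB10 knockdown, edgeR with Benjamini-Hochberg adjustment called 1751 genes (729 higher, 1022 lower). DESeq2 called 569 higher and 627 lower, a fit of the compared groups alone 1100 higher and 1053 lower, and without the untreated or treated control library 2 the count fell to 1076 or 1102. The unfolded protein response stood out, with 23 of 24 genes higher (median log2 1.20, camera adjusted p = 1.0e-24; adjusted p = 0.00384 with an estimated correlation). CHAC1, which degrades glutathione (4.66 ± 0.27), the pseudokinase TRIB3 (3.27 ± 0.20), HERPUD1 of endoplasmic reticulum degradation (2.51 ± 0.13), SESN2 (2.11 ± 0.14) and the chaperone HSPA5 (1.84 ± 0.10) led it. Cholesterol genes were higher in 11 of 22 (median 0.53, adjusted p = 2.77e-07; adjusted p = 0.0224 with an estimated correlation), with INSIG1 (2.23 ± 0.14) and HMGCS1 (1.99 ± 0.14). Immediate early genes were higher in 14 (median 0.51, adjusted p = 2.11e-07; adjusted p = 0.188 with an estimated correlation), inflammatory factors in 9 (median 1.06, adjusted p = 1.08e-05; adjusted p = 0.252 with an estimated correlation), with CXCL8 (4.18 ± 0.42) and VEGFA (1.15 ± 0.13), and cell cycle genes, which H2O2 lowered in both, in 7 (median 0.24, adjusted p = 0.00168; adjusted p = 0.605 with an estimated correlation). Adjusted over the list alone, 13 cholesterol, 17 immediate early, 11 inflammatory and 9 cell cycle genes passed. DDIT4 (2.94 ± 0.17) was higher, and TXNIP (-2.33 ± 0.15), the chromatin gene PRR12 (-1.84 ± 0.14), BMP4 (-1.78 ± 0.16), TOB1 (-1.71 ± 0.19), RREB1 (-1.69 ± 0.18) and ZNF503 (-1.68 ± 0.14), all regulators of growth or transcription, were lower. The p53 targets went both ways, 6 up and 4 down (adjusted p = 0.135), and IDH1 was not called (0.14 ± 0.12).

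With IDH1 knockdown, the interaction held 1380 genes in edgeR with Benjamini-Hochberg adjustment (524 higher, 856 lower; DESeq2 called 879; 175 higher and 128 lower with at least a 2-fold change). The count fell to 741 or 764 without the untreated or treated control library 2, to 812 without the untreated control library 1, and to 867 or 870 without the untreated knockdown library 1 or 2. Immediate early genes were higher in 13 of 26 (median log2 0.60, camera adjusted p = 8.78e-09; adjusted p = 0.185 with an estimated correlation), with EGR1 (1.53 ± 0.16) and FOSL1 (1.19 ± 0.12). Cell cycle genes, already low in untreated knockdown cells, were higher in 13 of 40 (median 0.49, adjusted p = 2.84e-07; adjusted p = 0.443 with an estimated correlation), with NUSAP1 (1.34 ± 0.24), and as a list fell less with H2O2 (median -0.70 in the knockdown, -0.99 in the control). Cholesterol genes were higher in 6 (median 0.21, adjusted p = 0.000147; adjusted p = 0.153 with an estimated correlation), with INSIG1 (1.41 ± 0.13), which fell less (-0.18 ± 0.09 in the knockdown, -1.59 ± 0.10 in the control), and the unfolded protein response in 4 with 1 lower (median 0.19, adjusted p = 0.00145; adjusted p = 0.216 with an estimated correlation), with TRIB3 (1.40 ± 0.19). The p53 targets were lower in 8 and higher in 2 (median -0.25, adjusted p = 0.0237; adjusted p = 0.354 with an estimated correlation), with ZMAT3 (-1.08 ± 0.13) and MDM2 (-0.78 ± 0.13), and collagens lower in 7 (median -0.17, adjusted p = 0.00275; adjusted p = 0.574 with an estimated correlation). Inflammatory factors were higher in 4 (adjusted p = 0.0237; adjusted p = 0.574 with an estimated correlation), with TNFAIP3, which dampens NF-kB (1.29 ± 0.15). Adjusted over the list alone, 16 immediate early, 17 cell cycle, 13 p53 and 13 collagen genes passed. The growth factor HBEGF (1.98 ± 0.27), CCDC85B (1.79 ± 0.15), a repressor of beta-catenin, and IQGAP3 (1.68 ± 0.22), a scaffold of dividing cells, were higher. PRR12 (-1.52 ± 0.14), TXNIP (-1.51 ± 0.14) and CTGF (-1.48 ± 0.13) were lower. So was IDH1 (-1.94 ± 0.22), the knocked-down target, with 73 and 85 reads in the untreated and 24 and 33 in the treated knockdown libraries. For IDH1, a deeper knockdown in the treated cells cannot be told from a different response to H2O2.

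**Figure D4:**
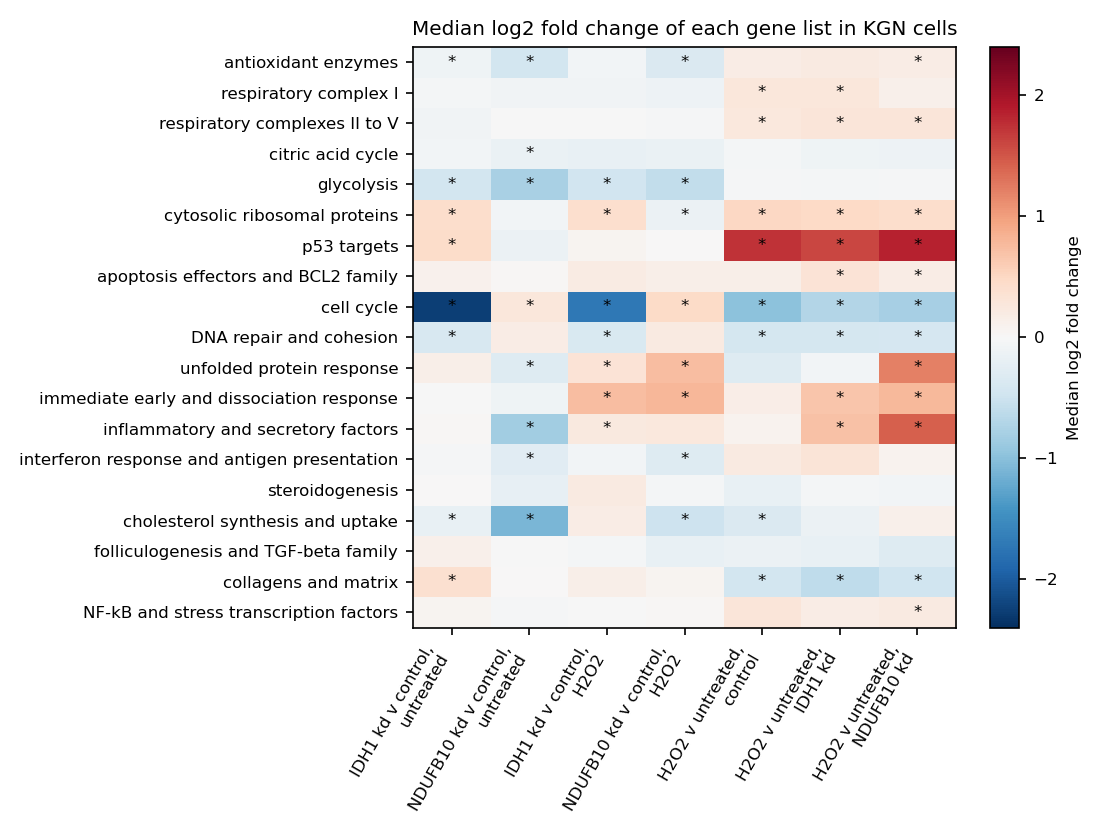
Median log2 change of each gene list with at least 10 tested genes (vertical axis) in the knockdown and H2O2 contrasts of KGN cells (horizontal axis); colour gives the median and a star an adjusted p under 0.05 in camera with the preset correlation. The cell cycle reaches -2.27 with IDH1 knockdown, cholesterol genes -1.09 with NDUFB10 knockdown and p53 targets 1.73 with H2O2.

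Under H2O2, the knockdowns were also compared with the treated control. The IDH1 knockdown changed 5492 genes in edgeR with Benjamini-Hochberg adjustment (2667 higher, 2825 lower), with IDH1 down by -6.59 ± 0.14, MKI67 by -3.16 ± 0.15 and 36 of 40 cell cycle genes lower (median log2 -1.72, camera adjusted p = 4.52e-22; adjusted p = 0.102 with an estimated correlation). TRIB3 (2.32 ± 0.14), FOSB (2.24 ± 0.17), the phosphatase DUSP8 (2.13 ± 0.20) and CHAC1 (1.87 ± 0.21) rose, as did 14 unfolded protein response genes with 1 lower (median 0.33, adjusted p = 3.89e-05; adjusted p = 0.102 with an estimated correlation) and 66 of 74 ribosomal genes with 1 lower (median 0.40, adjusted p = 9.33e-16; adjusted p = 0.131 with an estimated correlation). The NDUFB10 knockdown changed 6620 genes (3192 higher, 3428 lower), with NDUFB10 down by -4.92 ± 0.17, IDH1 by -1.38 ± 0.09 and SCD by -3.84 ± 0.09. CHAC1 (3.63 ± 0.19), TRIB3 (2.99 ± 0.14), CXCL8 (2.74 ± 0.17) and HSPA5 (1.51 ± 0.07) rose, and 21 of 24 unfolded protein response genes rose (median 0.75, adjusted p = 4.19e-10; adjusted p = 0.0433 with an estimated correlation). Cell cycle genes rose in 27 and fell in 3 (median 0.47, adjusted p = 3.02e-05; adjusted p = 0.347 with an estimated correlation), cholesterol genes fell in 16 and rose in 2 (median -0.50, adjusted p = 0.000229; adjusted p = 0.0611 with an estimated correlation), and antioxidant enzymes fell in 25 and rose in 8 (adjusted p = 0.00192; adjusted p = 0.0611 with an estimated correlation).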

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

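The tests of UMIs per captured molecule, of mixed RNA, of library scaling, of a link to sterol genes and of other splits of the animals were chosen only after the results they measure had been seen. The tests of few cells per animal and of rod photoreceptor genes were written before their values were known.

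Spread between animals was near 100% for somatic cell types and lower in oocytes, while no gene passed the age test in any of 6 types. The fitted coefficient of variation was 43.6% in oocytes and 100% to 106% in granulosa, stromal, smooth muscle, endothelial and T and NK cells. With 20 random cells per animal, the dispersion of oocytes reached at most 0.228 over 20 draws, against 0.19 with all cells and over 1.0 in the somatic types. Few cells per animal alone therefore did not raise the spread of oocytes to that of the somatic types. For somatic cells these draws cannot decide, because spike-in RNAs were missed in far more somatic cells than oocytes, as given next. Several UMIs counted per captured molecule remain a candidate explanation: spike-in RNAs were missing from a median of 61.28 percentage points more cells than a Poisson count of their mean gives in 31 somatic libraries, and from 3.79 points more in 7 oocyte libraries. A true difference in variability between animals was not tested and stays open. With each gene counted once per cell, the fitted coefficient was 7.5% in granulosa, 18.3% in stromal and 19.2% in smooth muscle cells. It was 1% in endothelial cells, T and NK cells and oocytes. These values cannot decide, because that setting also removes true differences in transcript level per cell and tests fewer genes.

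The number of age genes was also set against other splits of the same animals, and this says nothing about chance: age called 0 genes in 5 types, so 35 of 35 splits give at least as many by construction. In oocytes, another split gave 284 genes, which points to a structure of the samples unrelated to age (OF1, OF2, YF1 and YF3 against OF3, OF4 and YF4). Oocyte clusters differed along this split. One held 32.56% to 47.37% of the oocytes of OF3, OF4 and YF4 and 4.44% to 18.18% in the other animals. Another held 47.37% to 62.79% and 1.72% to 46.67%, and the remaining clusters overlapped. Whether the clusters gave the 284 genes was not tested. The highest other split gave 0 genes in granulosa and stromal cells, 1 in smooth muscle cells and 5 in endothelial cells. The edgeR counts at an unadjusted p under 0.05 were 232, 294, 423, 434 and 370 in these types, and DESeq2 called 6, 33, 36, 13 and 6.

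IDH1 was lower in the NDUFB10 knockdown libraries, by -1.52 in log2 untreated and -1.38 with H2O2. IDH1 knockdown RNA mixed into these libraries is argued against: it would need a share of 66.1% in untreated libraries and so leave NDUFB10 at 32.8 CPM, where the libraries held 3.64 CPM, or 11.09% of that level, and 6.08% with H2O2. Scaling of the libraries is argued against as well, since a wrong factor moves all genes of a library alike, while the log2 change of IDH1 minus that of the median gene was -1.541 untreated and -1.377 with H2O2. A shared fall with sterol synthesis genes stays open: H2O2 moved IDH1 by 0.145 ± 0.12 (SE) more in the knockdown than in the control, against a median of 0.53 for the cholesterol list. An effect of the NDUFB10 loss or of the knockdown reagent on IDH1 could not be told from these libraries.

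Genes of rod photoreceptors, which ovaries should lack, appeared in the medulla library of OF1, with 17804 UMIs or 3043 CPM over all 13 genes listed, among them SAG (728 CPM) and GNGT1 (457). The median library held 7.49 CPM. Whole cells of another tissue among the picked cells may explain most of it, since 87.26% of the UMIs lay in 9 of 81 cells. RNA spread over the library is a candidate explanation for the rest, since 100% of the other cells held such a UMI, against a median of 0% in the other somatic libraries. The same 13 genes occurred in a small-cell cortex library of YF3 (197 CPM) and a medulla library of OF2 (179). No biological explanation was tested.

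Several animals stood far from the others of their group. Such a gap was found in 13 of 86 groups of 4 animals. The cutoff gives about 1 in 20 by chance for normally distributed values. CPM was used here without logarithms, and several genes had a spread above their mean, so the rate by chance is not known. The genes had also been picked by their small p. In stromal cells, YF3 held CCDC141 at 358.108 and UBE4B at 891.291 CPM, and OF1 held C1orf109 at 90.297 CPM. CCDC141 at 0.218 CPM in OF1, over 0 UMIs in the other aged animals, is too low to say anything about that animal. In smooth muscle cells, YF3 held C11orf74 at 749.949 CPM, OF3 held C11orf74 at 7.614 and OF2 held FAS at 140.859. In endothelial cells, YF3 held YIPF4 at 1526.029 and CRTC3 at 3430.306 CPM, and YF1 held LYST at 65.296. The values of YF3 rest on 18 stromal, 14 smooth muscle and 11 endothelial cells. Its medulla library kept 0 of 96 cells, all its other somatic libraries stood apart before centring, and 64.46% of its somatic cells stayed unnamed. In oocytes, TMEM260 stood at 313.616 CPM in OF1. Smooth muscle cells made up 39.336% of the named somatic cells of YF1, and epithelial cells 5.093% of those of OF1. The response to H2O2 differed from the control in 1380 genes with IDH1 knockdown and in 1751 with NDUFB10 knockdown, by the edgeR interaction test. Spike-in RNAs, which entered no test of age or knockdown, took 11.53% of all UMIs.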

How the results depend on the processing

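The settings without centring, without libraries that stood apart, and with each gene counted once per cell, as well as camera under the other settings, were chosen after seeing the data; the others were planned. The cause of the changes below was not tested, except where a setting removes animals or genes by its own construction.

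The count of genes changed with age was 0 in edgeR in each of 6 cell types. DESeq2 called 6 genes in oocytes, 33 in granulosa, 36 in stromal, 13 in smooth muscle, 6 in endothelial and 17 in T and NK cells, and edgeR without the filter on low counts called 1, 18, 56, 95, 72 and 11. Leaving out the libraries that stood apart gave 1 gene in stromal cells, counting each gene once per cell gave 1 in endothelial and 25 in T and NK cells, and cell types without centring gave 4 in T and NK cells. Without single animals, the count ran from 0 to 1 in stromal cells (1 without YF3), from 0 to 1 in smooth muscle cells (1 without YF4), and from 1 to 79 in T and NK cells (1 without OF3, 3 without OF4, 26 without YF2, 79 without YF4), where the lone animal left in a group was assumed to vary like the others. In oocytes, granulosa and endothelial cells it stayed at 0. The 13 lists called with age fell to 0 with an estimated correlation. Of these, 9 held with the stricter cell filter, 9 of 11 with at least 20 cells per animal, 10 without centring, 9 without the libraries that stood apart, 3 of 12 with each gene counted once per cell, 1 of 6 with a single oocyte cluster (ribosomal genes) and 0 of 2 in the large-cell fraction of the cortex. Cholesterol genes in smooth muscle cells were lost with the stricter cell filter (adjusted p = 0.194).

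Without single animals, camera kept its preset-correlation calls in oocytes for complex I, complexes II to V and ribosomal genes, and in smooth muscle cells for cholesterol genes. Each other list call was lost without at least 1 animal. The citric acid cycle in oocytes reached an adjusted p of 0.201 without YF3 and was also lost without OF1, OF3 or YF1. Immediate early genes in oocytes reached 0.741 without OF1 (also lost without OF2, OF3 or YF3) and folliculogenesis genes 0.201 without YF3 (also without OF2, OF3, OF4 or YF4). In granulosa cells the cell cycle reached 0.295 without OF3 (also lost without YF4) and ribosomal genes 0.397 without OF2 (also without OF1, YF3 or YF4). In smooth muscle cells ribosomal genes reached 0.0986 without YF3 and collagens 0.276 without OF3 (also lost without OF4, YF2, YF3 or YF4). In endothelial cells immediate early genes reached 0.298 and interferon genes 0.466 without YF4, both also lost without OF3 or OF4, and interferon genes without YF1 or YF3. With each gene counted once per cell, complex I and ribosomal genes in oocytes stood at 0.952, and over their alternatives the adjusted p ran from 6.83e-08 to 0.952 and from 1.09e-20 to 0.952.

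Some named differences that had not passed their test changed sign. IDH1 in oocytes was -0.13 with a single oocyte cluster and ran from -0.15 to 0.33 without single animals (negative without OF2 or YF1). DCN in granulosa cells was -0.043 with each gene counted once per cell, and AMH 0.32 without centring. In stromal cells, ITPR1 was 0.20 and NDUFB10 0.42 with at least 20 cells per animal, NDUFB10 0.055 without centring, and IDH1 0.14 with equal weight for every cell. NDUFB10 in smooth muscle cells was -0.028 in DESeq2. In T and NK cells NDUFB10 was 0.02 without centring, 0.69 without libraries that stood apart and 0.31 with each gene counted once per cell. Without single libraries, NDUFB10 in the IDH1 interaction ran from -0.081 to 0.158.

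In KGN, requiring at least a 2-fold change left 1062 and 1078 genes for the IDH1 and NDUFB10 knockdowns untreated, 1152 and 1634 with H2O2, 2059, 2761 and 2654 for H2O2 in control, IDH1 and NDUFB10 knockdown cells, 303 and 481 for the interactions, and 1509 between the knockdowns. DESeq2 called 879 genes for the IDH1 interaction in place of 1380. Without single libraries that count ran from 741 to 1781 (812 and 741 without untreated control library 1 or 2, 867 and 870 without untreated IDH1 knockdown library 1 or 2, 764 without treated control library 2), and that of the NDUFB10 interaction from 1076 to 1534 against 1751 (1076 without untreated control library 2, 1102 without treated control library 2). The direction with more genes turned under at least 1 setting in 8 of the 10 contrasts, all but the NDUFB10 knockdown with H2O2 and H2O2 in control cells. Of 82 list calls, 13 held with an estimated correlation. The correlation of the knockdowns was 0.502 between the H2O2 groups in place of 0.394, where simulated unchanged groups with shared controls gave means of 0.572 and 0.509. Of 645 named KGN results, 585 kept their direction and side of the threshold under every setting, 57 lost their call under at least 1, and 1 reversed.

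The labels tie the replicate numbers of KGN to nothing that groups share, and they were not taken as pairs. Deviations of same-numbered libraries correlated at -0.05 to 0.36 over 15 pairs of groups, 4 of them above 0.1, with 0.179 to 0.36 among the IDH1 knockdown with H2O2 and both groups of the NDUFB10 knockdown, so something shared by some of them stays open. With the number as a block, the counts were 5526, 5353, 5680, 6808, 7311, 8603, 8288, 1545, 1952 and 6046 in the order knockdowns untreated, knockdowns with H2O2, H2O2 in control, IDH1 and NDUFB10 knockdown, interactions, and knockdown against knockdown, with 82 list calls and 4 target calls as before. Calls of single genes changed: of the 5340 genes called for the IDH1 knockdown untreated, 5329 were among the 5526. The macrophage settings were not run, because no aged animal held 10 macrophages. In somatic cell types, edgeR recovered at most 54.8% of simulated 16-fold changes, and the reason was not tested.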

Other observations

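The pancreas list was chosen after some of its genes had been seen in these libraries. Genes of the exocrine pancreas, which make digestive enzymes and are not part of any comparison, were found in most somatic libraries and most completely in those of YF1. The list stood at 622 CPM in the median of 31 somatic libraries. All 12 listed genes that the files name had UMIs in 4 of the 5, and the other, a small-cell cortex library with 5 kept cells, was left out for having under 20. The first small-cell cortex library of YF1 held 3031 CPM, led by PLA2G1B (942), CLPS (383), CPA1 (322) and CTRL (291). Libraries of the other animals held UMIs of 2 to 9 of the 12 genes, and in the highest of them, a small-cell cortex library of YF3, PLA2G1B made up 1538 of 1547 CPM. PLA2G1B also made up 792.32 of 792.52 CPM in a medulla library of OF2. In the medulla libraries of OF1 and YF1 it made up 304 of 343 and 1275 of 1497 CPM. In such libraries the value of the list is largely that of this gene.

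HMCN2, a matrix gene, had 0 to 5 reads in each of the 6 untreated KGN libraries, control and knockdowns alike, and 282 to 853 reads in each of the 6 treated with H2O2.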
